A study of Mus musculus with 2 samples.

How the data were processed

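Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed for 1 sample of mouse embryonic stem (ES) cells of the strain 129S1/SvImJ, together with 1 input sample, which is sheared chromatin sequenced without immunoprecipitation. Per the labels' protocols, the cells were held with 9 µM RO-3306, an inhibitor of the mitotic kinase CDK1, for 12 hours, washed free of it, and collected in mitosis 11 hours later. Chromatin was fixed for 10 min with 0.4% formaldehyde and sheared to about 300 bp. The antibody, of which 10 µg was used, was raised against histone H3.3 phosphorylated at serine 31 (H3.3S31ph). Libraries were made from 20 ng of DNA with 10 amplification cycles and sequenced as single reads of 50 bp. No molecular identifiers are described, so duplicate reads were not separable from independent fragments.

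The submitters' processing notes name Bowtie 1.0.0 and the genome build mm9. How reads were assigned to repeat types, how reads matching several types were treated and whether duplicates were removed is not given in the sources used here. The deposited tables hold raw read counts per repeat type for the ChIP and for the input, 1 table for each of 2 sequencing lanes. Rows are repeat types rather than genomic positions, so no coordinates were used. Each deposited table also holds the authors' log2 ratio of ChIP to input with a lower and an upper bound, and a conservative value that is the bound nearer 0, or 0 where the interval spans 0. Tested on the values, the deposited log2 ratio equals the log2 of the counts with 0.5 added to each, minus 1 constant per lane, to within 0.0005. The deposited bounds match a 90% interval computed from the same counts to within 0.0023. The constants are 0.31 in lane 1 and 0.29 in lane 2, which correspond to 1.24 and 1.22 ChIP reads per input read. What they were computed from is not given in the sources used here.

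All further values were computed from the raw counts. The lanes are runs of the same libraries and were summed, so each group has 1 sample and no test between conditions was possible. The ratio of a repeat is its share among all ChIP reads in the tables over its share among all input reads in the tables. The plan made before the data were examined named library totals where a file gives them and otherwise these table totals, and the files give no library totals. The constants recovered from the deposited log2 values were at first used as the main scale. That choice was made after values had been seen, among them the change of direction of GSAT_MM between the scales, so the main scale was returned to the planned table totals. The deposited scale is kept as an alternative chosen after seeing the data. The tables cover only part of each library, and abundant enriched repeats lower the ratio of all others on this scale. Each ratio has a 95% exact conditional (Clopper-Pearson) interval, and so has each share of reads. These intervals cover counting error only, and none of them measures the spread between cultures. Repeats with at least 100 input reads over both lanes were analysed further. They numbered 704 of 952 and held 99.9% of the input reads in the tables.

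Before the data were examined, 16 lists of repeats were fixed by name. The lists of young and other rodent L1 elements matched none of the rows, so these 2 lists have no values here. Whether rows under other names hold L1-related sequence was not examined. For each of the other 14 lists the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from the same 10 classes of read abundance. This percentile describes these libraries and is no test. Lists were written as name prefixes, and some prefixes took further families. The class I list took 15 analysed rows of RLTR40 to RLTR47, 8 rows stood in both the class I and class II lists, and the DNA transposon list took 9 analysed MER50-series rows, most of them long terminal repeats. Medians without these rows were computed as an alternative chosen after seeing the data. The repeats named were those with the 10 highest and 10 lowest ratios among repeats whose interval excluded 1 and whose lanes agreed in direction, up to 4 most abundant members of each list, and a fixed set of satellite, telomeric, ribosomal, retroviral and SINE (short interspersed element) names. Rows outside this rule are described as chosen after their values were seen.

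The tables held 6204712 ChIP and 4467116 input reads in lane 1, and 6030765 ChIP and 4389635 input reads in lane 2. The alternatives were each lane alone, other scalings, other read minimums and 1 read added to both counts. The scalings were the median repeat set to 1, table totals without the 5 most abundant repeats, old repeats set to 1 and the deposited scale. Old repeats were the 93 rows of the MIR and L2 list and the DNA transposon list. For list medians, old repeats set to 1 and the deposited scale were chosen after seeing the data. The computation of the ratio and its interval was tested on simulated data with 200 changed repeats among 704. Simulated counts carried counting error alone, and the scale between the libraries was taken as known. The test therefore covers neither an error of the scale nor the excess spread between lanes described below. Intervals held the true ratio for 96.7% of repeats. A 1.25-fold change was separated from 1 for 97.5% of 40 repeats and a 0.8-fold change for 90.0% of 40. Of 504 unchanged repeats, 3.8% had an interval that excluded 1. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.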

Results

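To map histone H3.3 phosphorylated at serine 31 (H3.3S31ph) over repetitive DNA in mitosis, reads from 1 H3.3S31ph ChIP-seq sample of mitotic mouse ES cells were compared with reads from 1 matched input sample. H3.3 is a histone H3 variant that is incorporated outside of DNA replication, and serine 31 is a residue that distinguishes it from the canonical H3 histones. The tables covered 952 repeat types, with 12235477 ChIP reads and 8856751 input reads over both lanes. A ratio is the share of a repeat among ChIP repeat reads over its share among input repeat reads. There were no biological replicates, so every interval given below is a 95% interval of counting error, and no difference has a replicate check.

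The telomeric repeat was the most enriched repeat of the table. The TTAGGG array, listed under its complementary unit as (CCCTAA)n, had 1025528 ChIP reads against 51711 input reads, a ratio of 14.4 (14.2 to 14.5). It rose from 0.584% of input repeat reads to 8.38% of ChIP repeat reads. The ratio of every other repeat with at least 100 input reads was 3.20 or lower. Of 704 such repeats, 55 had a ratio with an interval above 1, 560 had one below 1, and 89 had an interval that included 1. With the median repeat set to 1, 192 lay above and 135 below it. Only 8 had a ratio of at least 2, and 1 had a ratio of 0.5 or lower. Shares add up to a fixed total, so a gain of some repeats lowers the ratio of others. The median repeat had a ratio of 0.805 (log2 ratio -0.31), and counts and values relative to this median are given for several lists and named repeats below. On the scale recovered from the authors' deposited log2 values, an alternative chosen after seeing the data, every log2 ratio is higher by about 0.17, and 109 repeats had an interval above 1 and 392 below 1.

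**Figure D1:**
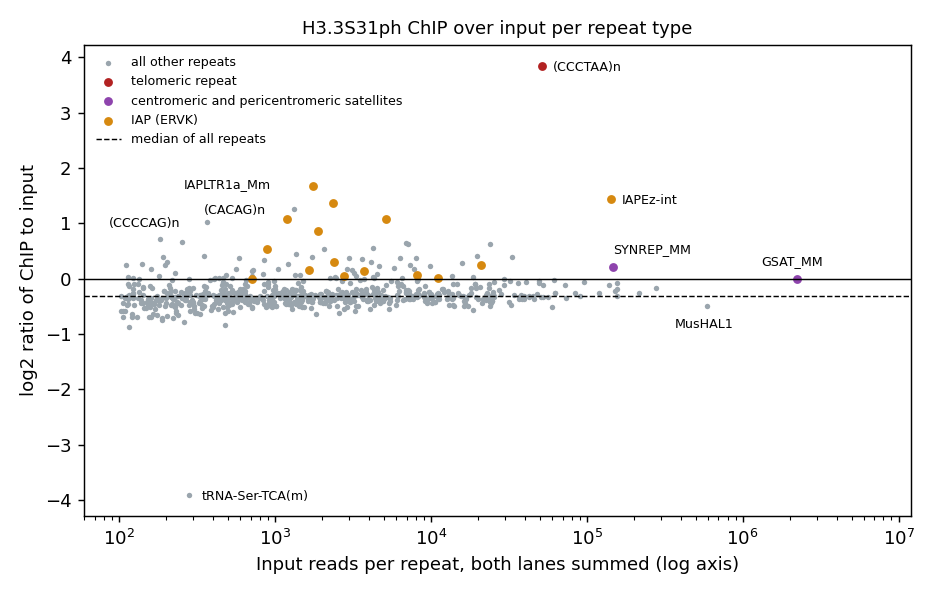
Log2 ratio of H3.3S31ph ChIP to input (vertical axis) against input reads per repeat, both lanes summed (horizontal log axis), for the 704 repeats with at least 100 input reads. The telomeric repeat (CCCTAA)n stands at 3.84, IAPEz-int at 1.45 and the major satellite GSAT_MM at -0.0044, while the median of all repeats (dashed line) is -0.31.

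Of the abundant satellites of mouse centromeric regions, the minor satellite was slightly enriched and the major satellite was not. The minor satellite entry SYNREP_MM, the repeat on which mouse centromeres are built, had a ratio of 1.15 (1.15 to 1.16). The major satellite GSAT_MM, which forms the pericentromeric heterochromatin, had a ratio of 0.997 (0.995 to 0.999) over 3071381 ChIP reads. Relative to the median repeat both lay higher, with log2 ratios of 0.52 for SYNREP_MM and 0.31 for GSAT_MM, and on the deposited scale they were 0.37 and 0.16. The direction of the major satellite against input thus depended on the scale. Every other scaling tried raises all log2 ratios, so none of them could have reversed the direction of the minor satellite. Centromeric and pericentromeric satellites together made up 27.0% of ChIP repeat reads and 26.8% of input repeat reads. CENSAT_MC, a further entry, had 1 ChIP read and 2 input reads, a ratio of 0.362 (0.0061 to 6.95). The median of the 2 measured entries stood at percentile 89.8 of random lists of like abundance.

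Of the other satellites, ZP3AR had a ratio of 1.46 (1.41 to 1.52), MMSAT4 one of 0.869 (0.843 to 0.897) and MurSatRep1 one of 0.827 (0.805 to 0.849). Relative to the median repeat, MMSAT4 lay above it at a log2 ratio of 0.11, while MurSatRep1, at 0.038, was not separable from it. The list median stood at percentile 78.0. Among the ribosomal RNA entries, the large subunit LSU-rRNA_Hsa had a ratio of 1.13 (1.10 to 1.16), whereas the intervals of the small subunit SSU-rRNA_Hsa, at 1.01 (0.971 to 1.05), and of 5S, at 0.968 (0.891 to 1.05), included 1. All 3 lay above the median repeat. Their median stood at percentile 95.8, and at 87.9 for the 2 entries with at least 1000 input reads.

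Intracisternal A particle (IAP) elements are endogenous retroviruses of the ERVK class that are silenced by H3K9 methylation in ES cells. Among the transposon lists with measured members, which hold no L1 elements, theirs had the highest median log2 ratio. Of 15 IAP entries, 12 had an interval above 1, 3 included 1, and all 15 lay above the median repeat. The highest ratios, from 1.81 to 3.20, were those of the 6 entries of the IAPEz, IAPLTR1 and IAPLTR2 types, a grouping made after the values were seen, and the other 9 had ratios from 1.00 to 1.46. The internal sequence IAPEz-int, which held 81.8% of the IAP reads in the ChIP, had a ratio of 2.73 (2.71 to 2.75). The long terminal repeats (LTRs), the promoter ends of the elements, had ratios of 3.20 (3.04 to 3.37) for IAPLTR1a_Mm, 2.59 (2.48 to 2.72) for IAPLTR1_Mm, 2.11 (2.04 to 2.18) for IAPLTR2_Mm, 2.11 (1.97 to 2.25) for IAPLTR2a and 1.81 (1.72 to 1.91) for IAPLTR2b. Among the IAPEY entries, IAPEY3-int had a ratio of 1.19 (1.17 to 1.21), and IAPEy-int, at 1.01 (0.986 to 1.04), was not separable from 1. IAP elements rose from 2.36% of input repeat reads to 5.42% of ChIP repeat reads. The median log2 ratio of 0.30 lay above the medians of all 10000 random lists. Pooling the reads of the list gave a log2 ratio of 1.20, because IAPEz-int dominated the pool.

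Other endogenous retroviruses were mixed. In the list of other class II elements, 14 of 57 entries had an interval above 1, 32 below 1, and 11 included 1. Relative to the median repeat, 39 lay above it and 5 below it. The internal sequences RLTR10-int and MMETn-int, the latter belonging to the early transposon family, had ratios of 1.33 (1.31 to 1.35) and 1.32 (1.30 to 1.34). RLTR45-int, which stands in both this list and the class I list, had 0.938 (0.920 to 0.956), although it lay above the median repeat at a log2 ratio of 0.22. The older RMER17B and RMER19B had 0.848 (0.834 to 0.862) and 0.819 (0.808 to 0.831), close to the median repeat at 0.075 and 0.026. In the class I list, 13 of 33 entries had an interval above 1 and 13 below 1, while 27 lay above and 3 below the median repeat. RLTR6-int reached 1.54 (1.52 to 1.56) and MMERGLN-int 1.22 (1.20 to 1.25), while MuRRS4-int had 0.883 (0.862 to 0.905), which lay above the median repeat at a log2 ratio of 0.13. Without the rows that the class I prefixes took from other families, 9 of 18 entries had an interval above 1 and 7 below 1, an alternative chosen after seeing the data. The medians, -0.14 for class II and 0.0060 for class I on the log2 scale, exceeded those of all 10000 random lists. The class I median was not separable from the input level, at -0.019 in lane 1 and 0.031 in lane 2, and with at least 1000 input reads the class II median was -0.22, at percentile 99.8.

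The class III elements went the other way. All 5 MT2 entries, the LTRs of MERVL and its relatives, had an interval below 1, with ratios of 0.774 (0.764 to 0.785) for MT2A, 0.779 (0.760 to 0.800) for MT2_Mm, 0.812 (0.797 to 0.826) for MT2B and 0.823 (0.797 to 0.849) for MT2B2. Relative to the median repeat, 3 of the 5 lay below it, while MT2B and MT2B2 lay at log2 ratios of 0.012 and 0.032. All 59 mammalian apparent LTR retrotransposon (MaLR) entries had an interval below 1, while 18 lay below and 6 above the median repeat. Their most abundant members MTD, MTC, ORR1E and ORR1D1 had ratios of 0.807, 0.804, 0.787 and 0.796. Once the median repeat was set to 1 the list median was -0.018, so the MaLR elements lay near the bulk of repeats. The class III and MaLR medians stood at percentiles 5.67 and 0.410 of random lists, and that of class III was 2.52 in lane 1 and 9.61 in lane 2.

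**Figure D2:**
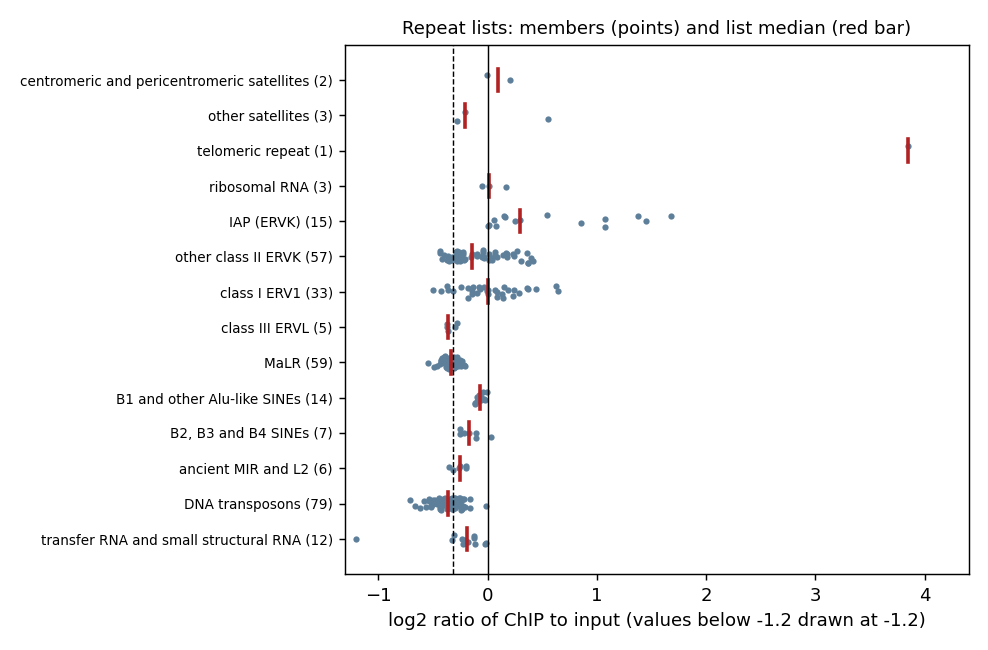
Log2 ratio of ChIP to input (horizontal axis) for each member with at least 100 input reads (points, lanes summed) of the 14 lists with measured members, with the list median as a red bar and the number of members in parentheses. The solid line marks the input level and the dashed line the median of all repeats at -0.31. The IAP list median is 0.30, and every member lies above 0.

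Most of the B1 to B4 short interspersed elements lay between the median repeat and the input level. Of 14 entries of the Alu-like B1 family, 13 had an interval below 1 and 1 included 1, yet all 14 lay above the median repeat. Ratios were 0.985 (0.974 to 0.995) for B1_Mus2, 0.959 (0.951 to 0.967) for B1_Mus1, 0.945 (0.932 to 0.958) for B1_Mm, 0.924 (0.913 to 0.935) for B1F and 0.922 (0.914 to 0.931) for PB1D10. The list median of -0.069 on the log2 scale stood at percentile 99.8 of random lists, and it turned to 0.24 with the median repeat set to 1. In the B2, B3 and B4 list, 1 entry lay above 1 and 6 below 1. B2_Mm1a had 1.02 (1.00 to 1.04), B2_Mm2 0.930 (0.923 to 0.936), B3 0.887 (0.882 to 0.891), B3A 0.862 (0.856 to 0.868) and B4A 0.839 (0.834 to 0.844). All 7 entries lay above the median repeat, from 0.059 for B4A to 0.35 for B2_Mm1a.

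Old repeats that no longer move served as a comparison. All 6 MIR and L2-type entries had an interval below 1, while 4 lay above and 1 below the median repeat. L2 had a ratio of 0.805 (0.794 to 0.816), MIRb 0.836 (0.828 to 0.845), MIR 0.841 (0.832 to 0.850) and MIRc 0.871 (0.857 to 0.885), and relative to the median repeat the 3 MIR entries lay at log2 ratios of 0.056, 0.064 and 0.11. In the DNA transposon list 73 of 79 entries lay below 1 and 0 above it, among them Tigger7 at 0.775, URR1A at 0.797, MER5A at 0.801 and URR1B at 0.811. Relative to the median repeat only 19 lay below it and 1 above it, so most were not separable from the bulk of repeats. Without the 9 rows that its prefixes took from other names, 64 of 70 lay below 1. The medians of these lists stood at percentiles 61.8 and 3.28, the latter being 7.45 in lane 1, 1.00 in lane 2 and 0.50 with at least 1000 input reads. In the list of transfer RNA and small structural RNA genes, 7 of 12 entries lay below 1, with 0.920 (0.887 to 0.955) for BC1_Mm, 0.882 (0.818 to 0.950) for 7SK, 0.856 (0.799 to 0.918) for tRNA-Ala-GCY_ and 0.851 (0.790 to 0.916) for U6. Relative to the median repeat 5 lay above it and 1 below it, and the 4 named entries stood at log2 ratios of 0.19, 0.13, 0.089 and 0.080. Its median stood at percentile 99.2, at 99.5 in lane 1, 94.3 in lane 2 and 91.45 for the 4 entries with at least 1000 input reads.

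The repeats with the 10 highest ratios held 3 further simple repeats beside the telomeric one. (CACAG)n had a ratio of 2.39 (2.25 to 2.55) over 1335 input reads, (CCCCAG)n had 2.04 (1.81 to 2.31) over 365 input reads and (CCCCG)n had 1.65 (1.38 to 1.97) over 183 input reads. At the other end, tRNA-Ser-TCA(m) had 26 ChIP reads against 282 input reads, a ratio of 0.0667 (0.0428 to 0.0999). The next lowest were UCON5 at 0.549 (0.411 to 0.731), C573_MM at 0.559 (0.487 to 0.642) and MER97a at 0.580 (0.482 to 0.698). The AT-only unit (TTAAA)n had 0.598 (0.480 to 0.743) and (CATAT)n had 0.617 (0.488 to 0.779). UCON7, Tigger12, Helitron2Na_Mam and LTR52-int had ratios between 0.610 and 0.622. Apart from C573_MM, with 479 input reads, these low entries rested on 116 to 282 input reads each. Among 77 simple repeats other than the telomeric one, the log2 ratio went up with the share of G and C in the unit (Spearman's rho 0.775 across repeats, which are not independent replicates).

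The 2 lanes gave close ratios for most repeats where reads were many. Over the 406 repeats with at least 1000 input reads, the log2 ratios differed by a median of 0.035 and at most 0.28. The telomeric log2 ratio was 3.84 in both lanes, that of IAPEz-int was 1.45 in both, and that of GSAT_MM was -0.0021 and -0.0067. In each lane, 3 named repeats had a log2 ratio outside the 95% interval of the summed lanes and 65 had one inside it. Counting error alone would place about as small a share outside. In lane 1 and lane 2, the 3 were ZP3AR at 0.63 and 0.47, LSU-rRNA_Hsa at 0.22 and 0.12, and MTD at -0.32 and -0.30. Over 704 repeats Pearson's r of the lane ratios was 0.886 and Spearman's rho 0.667, and over the 406 with at least 1000 input reads they were 0.979 and 0.870. Again this is across repeats. Read counts of the lanes differed by slightly more than counting error, with a chi-square of 905.0 on 708 degrees of freedom (p = 6.75e-07) for the ChIP and 909.6 on 703 (p = 2.05e-07) for the input. In both libraries (TA)n and AT_rich contributed most, with 1.12 and 1.06 times more ChIP reads and 1.13 and 1.05 times more input reads in lane 1 than the totals gave. These rows were chosen after their values were seen. By the deposited conservative values, the authors' deposited table put 127 repeats above and 388 below 0 in lane 1, and 123 above and 383 below 0 in lane 2. These counts cover all 952 rows without a read minimum, in single lanes, with 90% intervals and on the deposited scale. They are therefore not directly comparable with the counts given above.

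**Figure D3:**
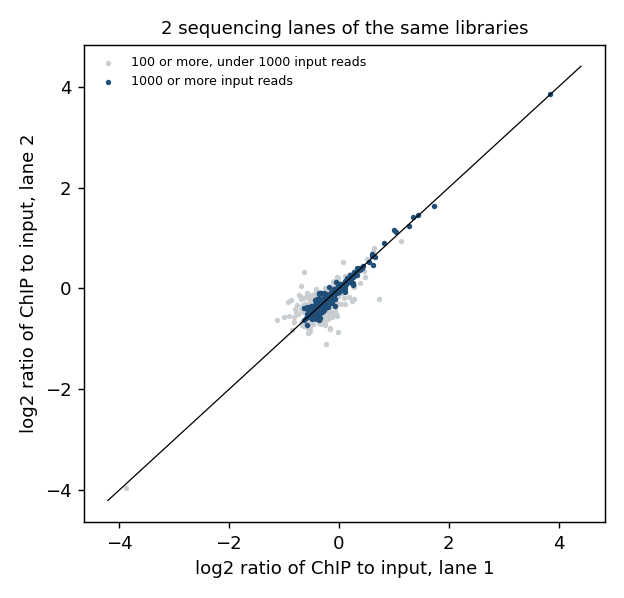
Log2 ratio of ChIP to input in lane 1 (horizontal axis) and lane 2 (vertical axis) of the same libraries, for repeats with at least 100 but under 1000 input reads (grey) and with 1000 or more (blue), with the line of equality. The lanes lie closer together where reads are many, with Spearman's rho of 0.870 across the 406 repeats with at least 1000 input reads and 0.667 across all 704.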

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

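The scale between the libraries was the choice that moved most values, since it adds 1 constant to every log2 ratio, and the direction of small ratios against input depended on it. Setting the median repeat to 1 added 0.31, setting old repeats to 1 added 0.30, leaving out the 5 most abundant repeats added 0.20 and the deposited scale added 0.17. The deposited scale, and old repeats set to 1 for list medians, were chosen after seeing the data. Old repeats are the MIR and L2 list and the DNA transposon list, so both medians lie near 0 on that scale by construction. The deposited scale had at first been the main setting, before the return to the planned table totals. Repeats with an interval above 1 numbered 55 with table totals, 192 with the median repeat set to 1, 182 with old repeats set to 1, 125 without the 5 most abundant and 109 on the deposited scale. Those below 1 numbered 560 with table totals, and 135, 161 and 338 under the first 3 of these alternatives. With at least 1000 input reads 344 of 406 lay below 1, against 560 of 704 with the main minimum. Without a read minimum 21 repeats, in place of 8, had a ratio of at least 2. The added ones each had under 100 input reads. Medians of lists became, with the median repeat set to 1, 0.41 for centromeric satellites, 4.16 for the telomeric repeat, 0.33 for ribosomal RNA, 0.17 for other class II, 0.32 for class I, -0.046 for class III, -0.018 for MaLR, 0.24 for B1, 0.14 for B2, B3 and B4, 0.060 for MIR and L2, -0.046 for DNA transposons and 0.12 for small RNA genes. With old repeats set to 1 they were 0.40 for centromeric satellites, 4.15 for the telomeric repeat, 0.32 for ribosomal RNA, 0.16 for other class II, 0.31 for class I, -0.058 for class III, -0.030 for MaLR, 0.23 for B1, 0.13 for B2, B3 and B4, 0.048 for MIR and L2, -0.057 for DNA transposons and 0.11 for small RNA genes. Without the 5 most abundant repeats they were 0.30 for centromeric satellites, 4.05 for the telomeric repeat, 0.22 for ribosomal RNA, 0.060 for other class II, 0.21 for class I, -0.16 for class III, -0.13 for MaLR, 0.13 for B1, -0.051 for MIR and L2, -0.16 for DNA transposons and 0.010 for small RNA genes. On the deposited scale they were 0.27 for centromeric satellites, 4.01 for the telomeric repeat, 0.18 for ribosomal RNA, 0.026 for other class II, 0.17 for class I, -0.19 for class III, -0.16 for MaLR, 0.10 for B1, -0.085 for MIR and L2, -0.19 for DNA transposons and -0.024 for small RNA genes. Within the range or interval of their members, the median repeat set to 1, old repeats set to 1, leaving out the 5 most abundant and the deposited scale gave 0.61, 0.60, 0.50 and 0.46 for IAP and 0.11, 0.10, 0.00080 and -0.034 for other satellites, and the last 2 settings gave 0.029 and -0.0051 for B2, B3 and B4. Summing reads moved the IAP value to 1.20, and lane 1 alone moved class III to -0.38.

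Among named repeats with an interval below 1, the log2 ratio turned positive with the median repeat set to 1, at 0.13 for 7SK, 0.20 for B1F, 0.23 for B1_Mm, 0.25 for B1_Mus1, 0.29 for B1_Mus2, 0.21 for B2_Mm2, 0.14 for B3, 0.099 for B3A, 0.059 for B4A, 0.19 for BC1_Mm, 0.31 for GSAT_MM, 0.064 for MIR, 0.056 for MIRb, 0.11 for MIRc, 0.11 for MMSAT4, 0.012 for MT2B, 0.032 for MT2B2, 0.0036 for MTD, 0.13 for MuRRS4-int, 0.038 for MurSatRep1, 0.20 for PB1D10, 0.22 for RLTR45-int, 0.075 for RMER17B, 0.026 for RMER19B, 0.080 for U6, 0.011 for URR1B and 0.089 for tRNA-Ala-GCY_. With old repeats set to 1 it was 0.12 for 7SK, 0.19 for B1F, 0.22 for B1_Mm, 0.24 for B1_Mus1, 0.28 for B1_Mus2, 0.20 for B2_Mm2, 0.13 for B3, 0.088 for B3A, 0.048 for B4A, 0.18 for BC1_Mm, 0.30 for GSAT_MM, 0.053 for MIR, 0.044 for MIRb, 0.10 for MIRc, 0.10 for MMSAT4, 0.00070 for MT2B, 0.021 for MT2B2, 0.12 for MuRRS4-int, 0.027 for MurSatRep1, 0.19 for PB1D10, 0.21 for RLTR45-int, 0.064 for RMER17B, 0.014 for RMER19B, 0.069 for U6 and 0.078 for tRNA-Ala-GCY_. Without the 5 most abundant repeats it was 0.021 for 7SK, 0.089 for B1F, 0.12 for B1_Mm, 0.14 for B1_Mus1, 0.18 for B1_Mus2, 0.097 for B2_Mm2, 0.029 for B3, 0.083 for BC1_Mm, 0.20 for GSAT_MM, 0.0031 for MIRc, 0.00080 for MMSAT4, 0.023 for MuRRS4-int, 0.086 for PB1D10 and 0.11 for RLTR45-int. On the deposited scale it was 0.054 for B1F, 0.086 for B1_Mm, 0.11 for B1_Mus1, 0.15 for B1_Mus2, 0.063 for B2_Mm2, 0.048 for BC1_Mm, 0.16 for GSAT_MM, 0.052 for PB1D10 and 0.076 for RLTR45-int. Of ChIP repeat reads, centromeric satellites held 3.51% without the 5 most abundant repeats, which takes GSAT_MM out of the list as well, and 30.4% without simple repeats and low-complexity rows. IAP elements held 1.81% in the first case, which takes out IAPEz-int, 6.11% in the second, and 5.40% and 5.44% in lane 1 and lane 2. The telomeric repeat is left out in both cases and has no value there. Each group holds 1 sample, so replicates could not be left out in turn. Without a read minimum Pearson's r between the lanes was 0.427.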

Other observations

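Repeats outside the fixed lists and the simple repeats mostly lay below input, as did most repeats of the table. Of 339 such entries with at least 100 input reads, 303 had an interval below 1 and 6 an interval above 1, while 74 lay below and 43 above the median repeat. The following were chosen after their values were seen. LTRIS2 had a ratio of 1.55 (1.51 to 1.60), ERVB4_2-LTR_MM 1.59 (1.37 to 1.85) and ERVB7_1-LTR_MM 1.45 (1.37 to 1.53), all of them LTR entries by name. In the class I list the LTR RLTR1B reached 1.56 (1.52 to 1.61). MusHAL1, which took 589504 input reads, more than any entry but GSAT_MM, had a ratio of 0.708 (0.705 to 0.710), and YREP_Mm had 0.664 (0.632 to 0.698). The low-complexity rows lay apart, at 1.32 (1.24 to 1.40) for GC_rich and 0.699 (0.691 to 0.707) for AT_rich. Simple repeats that differ from the telomeric unit by 1 substituted or deleted base had 323 ChIP and 272 input reads in 7 rows. Their pooled log2 ratio was -0.22 (-0.46 to 0.020). All 7 rows had fewer than 100 input reads, below the minimum used elsewhere. Of these, (TAGGG)n stood apart with 76 ChIP and 27 input reads, a ratio of 2.04 (1.30 to 3.29).

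All tests of explanations below were chosen after the result was seen. The telomeric log2 ratio of 3.84 was set against 2 technical explanations. Base composition predicted that other simple repeats with the same G and C share would come near it, but among 14 of them the median was -0.23 and the highest, (CAGT)n, had 0.17. The telomeric log2 ratio was 3.84 or more under every setting tried, with 3.84 in each lane. Every other scaling tried raises all log2 ratios, so none of them could have lowered it, and its height against input stays tied to the scale. A scale moves all repeats alike, however, so the distance to the next highest log2 ratio, 1.68 with table totals, does not come from it. An immunoprecipitation with another antibody or of total H3.3 was not analysed here, so whether the signal follows the phosphorylated residue, the amount of H3.3 or the recovery of telomeric chromatin stays open. The presence of H3.3S31ph on telomeric chromatin is the biological explanation the design offers, and it remains a hypothesis in 1 sample.

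Simple repeats other than the telomeric one had a log2 ratio that went up with their G and C share (rho 0.775 over both lanes, 0.709 in lane 1 and 0.723 in lane 2). The median was -0.39 (-0.48 to -0.26) for 27 units under 40%, -0.25 (-0.34 to -0.19) for 22 units from 40 to 50% and 0.019 (-0.10 to 0.25) for 28 units above 50%. The GC_rich row lay 0.91 above the AT_rich row, the same trend in low-complexity rows. GC-dependent recovery of fragments in the ChIP library is a candidate explanation. GC-rich repeats may instead lie in chromatin with more of the mark. Both explanations predict the rho of 0.775 and the difference of 0.91, so without genomic positions they cannot be told apart. The ratios of (CCCCG)n, (CCCCAG)n, (CACAG)n, (TTAAA)n and (CATAT)n, and those of families with a strong base composition, are open to the same doubt.

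The entry tRNA-Ser-TCA(m) had 26 ChIP and 282 input reads. Counting error leaves its log2 ratio at -3.32 or lower. The other 58 tRNA rows, leaving out the one other entry with the suffix (m), pooled to a log2 ratio of -0.18 (-0.25 to -0.11), which argues against a comparably low recovery of tRNA sequences in general. A possible explanation is that the suffix marks mitochondrial sequence and that its reads came from mitochondrial DNA, which carries no histones. The other entry with that suffix, tRNA-Leu-TTA(m), had 1 ChIP and 2 input reads, a ratio of 0.362 (0.0061 to 6.95), too few to decide.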
